A study of Mus musculus with 8 samples.

How the data were processed

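Gene expression was measured on Affymetrix Mouse Genome 430 2.0 arrays in long-term hematopoietic stem cells of the mouse, the bone marrow cells that renew themselves and give rise to all blood lineages. Per the labels' protocols, the cells were lineage-negative, c-Kit- and Sca-1-positive cells without Flk2 or CD34, sorted in 2 passes by flow cytometry. RNA of 22000 to 25000 cells per sample went through a double amplification and was biotin-labelled before hybridisation. The sources give the age of the old mice as 22 to 23 months. The age of the young mice is not given in the sources used here. The protocol text mentions old mice under all 8 samples, so the age group was taken from each sample's source label.

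The deposited table gives 1 processed intensity for each of 45101 probe sets on each of 8 arrays. How the authors summarised the probes, subtracted background or scaled the arrays is not given in the sources used here. The deposited intensity is on a linear scale with 1 decimal, and 4.31% of the values lie below 0. The medians of the arrays differed by 0.23 on the log2 scale. No column of the table was left out. The number of arrays limits the precision, since processed intensities carry no counts.

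The rule set before the data were examined was to add quantile normalization if the medians differed by more than 0.2 on the log2 scale, and it was therefore applied. Normalized intensities under the pooled 20th percentile (7.93) were set to that value and log2 was taken. A probe set was tested if at least 3 of the 8 arrays lay above the pooled 50th percentile (23.6), which left 24337 probe sets after removal of the 64 control probe sets. The 5 old arrays were compared with the 3 young arrays in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and an intensity trend, as a two-sided test with Benjamini-Hochberg adjustment and a threshold of 0.05. The replicate numbers follow accession order and pair no samples. The labels name 5 old and 3 young mice, but do not say whether each array holds the cells of 1 mouse, so the p-values measure the spread between these arrays.

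The table names probe sets by identifier alone, and no table pairing them with genes was used here. The 28 gene lists and 11 lists of cell type markers that had been fixed in advance were therefore not tested. The rule for named genes was reduced to 2 probe sets in each direction, those with the largest log2 difference among called probe sets whose old and young arrays did not overlap. Named transcripts appear only where a control probe set carries the name in its own identifier. For those, an exact two-sided permutation test over the 56 splits of the arrays was used, whose smallest possible p is 0.0179.

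Each array title begins with a serial number, whose meaning the labels do not give. Old arrays 3, 4 and 5 and young array 1 have consecutive numbers and the other 4 arrays do not. After the data had been seen, this grouping was added as a block to the age comparison. Age was also compared within each of the 2 sets of arrays, and the blocked fit was repeated without each array and with young 2 and 3 averaged.

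The fit was tested on simulated data with the means and residual spread of the real probe sets and 200 changed probe sets. It recovered 48 of 66 changes of 4-fold, 5 of 67 of 2-fold and 0 of 67 of 1.5-fold, with 2 false calls among the unchanged probe sets. The simulated noise was independent between arrays and between probe sets. The false calls therefore say nothing on differences shared by groups of real arrays. Alternatives covered the normalization, the floor, the filter, the variance model, array weights, the threshold, the class of probe set and each array left out.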

Results

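The study compared the transcripts of hematopoietic stem cells from old and young mice, to describe how these cells change with age. Processed intensities of 45101 probe sets were available for 5 arrays of old and 3 arrays of young stem cells. The median intensity per array lay between 21.4 and 25.1, and between 22.1% and 24.1% of the probe sets were above an intensity of 100.

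Probe sets passed in both directions between the old and the young arrays. Of 24337 probe sets tested, 70 were higher and 34 were lower in old stem cells at an adjusted p under 0.05 in limma. The changes that passed were large. In the simulated data few changes of 2-fold passed (5 of 67), so this size is largely set by what the test could reach. The median difference on the log2 scale was 2.24 for the higher and -2.17 for the lower probe sets, and 69 of the 70 and all 34 differed by at least 2-fold. In each of the 104 probe sets the old and young arrays did not overlap. Among all tested probe sets, 7.13% had no overlap between the groups, where chance gives 3.57%. At an unadjusted p under 0.05 there were 2506 probe sets, where 1217 would be expected without differences. Neither share was particular to age, since other divisions of the arrays into 5 and 3 gave more. Of the 55 others, 9 had more probe sets at an unadjusted p under 0.05, up to 6039, and 8 had more without overlap, up to 18.02%.

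The higher probe sets were spread over the range of expression. By the average of the old and the young mean, 30 lay in the lowest tertile, 23 in the middle and 17 in the highest. Of the lower probe sets, 23 lay in the lowest tertile, 10 in the middle and 1 in the highest. Of the higher probe sets, 7 were at the floor on every young array, and 5 of the lower ones were at the floor on every old array. Differences against the floor are lower bounds.

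Among the probe sets that passed, the largest increases were in those listed as 1450653_AT and 1421065_AT. The first had a log2 intensity of 9.92 ± 1.86 (SD, n = 5) in old and 4.89 ± 0.18 (SD, n = 3) in young stem cells, a difference of 5.03 (SE 0.87, limma adjusted p = 0.042). Its deposited intensity was 24.5 to 35 on the young arrays. On the old arrays it was 4571 and 3875 in old 1 and 2 but 350 to 388 in old 3 to 5. The second had 9.51 ± 1.79 (SD, n = 5) in old and 4.53 ± 0.34 (SD, n = 3) in young cells, a difference of 4.98 (SE 0.84, limma adjusted p = 0.039). It had the same division among the old arrays, with 3073 and 3056 in old 1 and 2 and 272 to 304 in old 3 to 5. The mean intensity of old 1 and 2 was 11.6 times that of old 3 to 5 for the first and 10.8 times for the second.

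Among the probe sets that passed, the largest decreases were in those listed as 1422247_A_AT and 1426816_AT. The first had 3.60 ± 0.93 (SD, n = 5) in old and 7.80 ± 1.71 (SD, n = 3) in young cells, a difference of -4.20 (SE 0.72, limma adjusted p = 0.041), with 840 on young array 1 and 105 and 119 on young arrays 2 and 3. Old 3, 4 and 5 were at the floor, so the size of this difference depends on the floor. The second was at the floor on all 5 old arrays (deposited intensity -0.6 to 6.6) and had 98.5 to 198 on the young arrays. It was at least 17.1-fold lower in old cells (limma adjusted p = 0.00069) and had the smallest adjusted p of all probe sets. At the floor its old arrays had no spread, and with the floor at the 5th percentile the limma adjusted p was 0.026. The other 3 each failed to pass in 12 of 24 alternative analyses, with limma adjusted p up to 0.23. The filter dropped 1426816_AT wherever a young array was left out, so its certainty cannot be ranked against theirs.

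**Figure D1:**
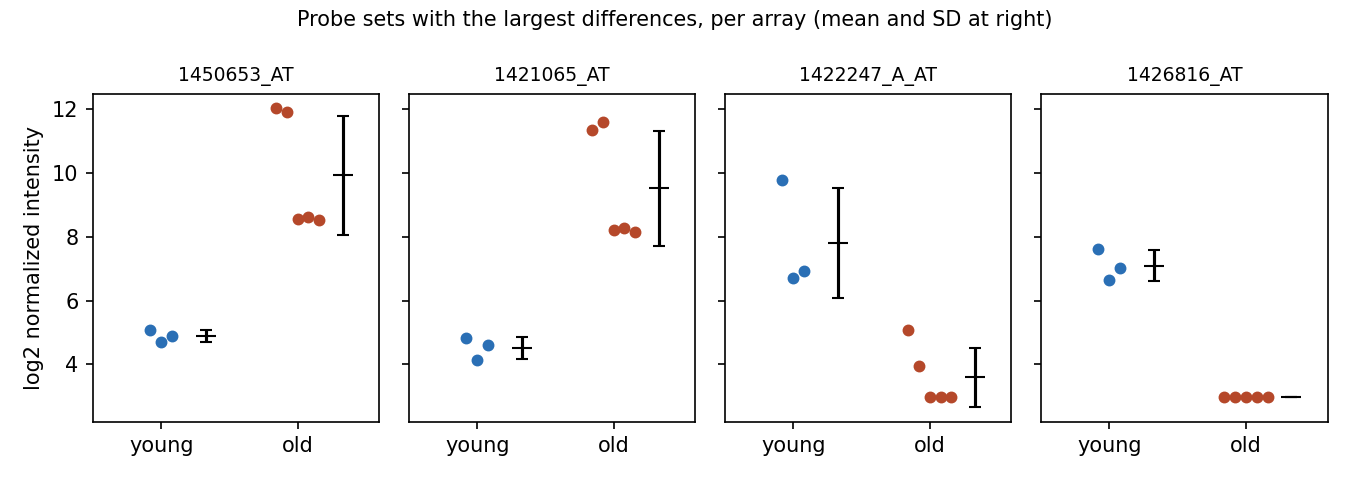
Log2 normalized intensity (vertical axis) of 4 probe sets on each young (blue) and old (red) array, with mean and SD as black bars at the right of each group. All old arrays lie above the young ones in the first 2 panels and below them in the last 2, and the old arrays sit at the floor in 1426816_AT, as do old 3, 4 and 5 in 1422247_A_AT.

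The arrays also differed in ways that age did not describe. The first principal component held 39.0% of the variance and separated old 1 (score 113) and old 2 (36.6) from old 3, 4 and 5 (-65.1, -38.3 and -30.7) and young 1 (-40.1). The second held 29.6% and separated young 2 and 3 (74.0 and 78.8) from the other arrays, young 1 included (-6.72). Across probe sets, which are not independent replicates, young 1 correlated at r = 0.94 to 0.95 with old 3 to 5 and at 0.91 and 0.90 with young 2 and 3. Young 2 and 3 were the closest pair of all 28, with r = 0.99 and a root mean square log2 difference of 0.308, against 0.435 for the next pair. The median SD per probe set was 0.46 on the log2 scale among the 5 old and 0.29 among the 3 young arrays.

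**Figure D2:**
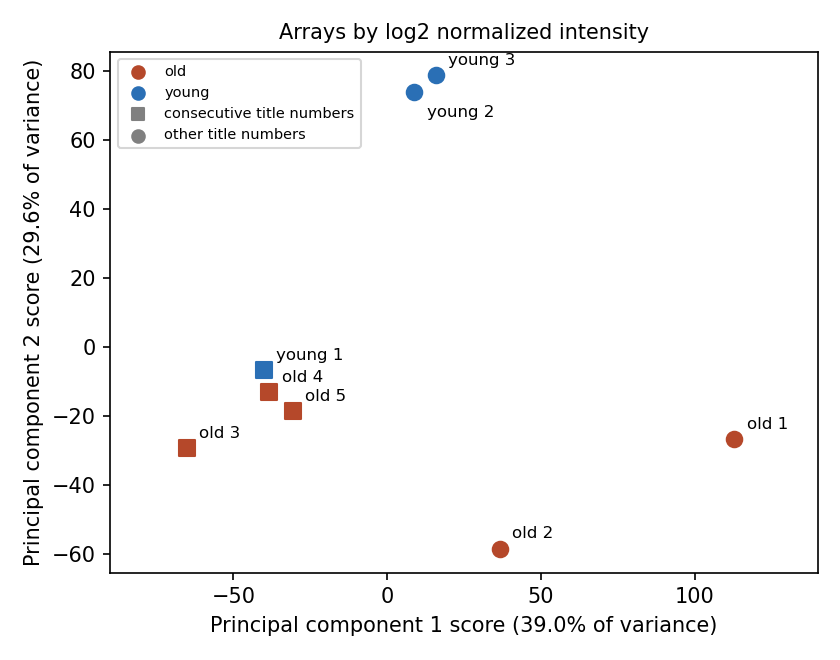
Scores of the 8 arrays on principal components 1 and 2 of the log2 normalized intensities, without units. Squares are the 4 arrays with consecutive title numbers (old 3, 4 and 5 and young 1), which lie together at the left, while young 2 and 3 lie apart at the top.

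Old 3, 4 and 5 and young 1 carry consecutive serial numbers in their titles. With this set of arrays as a block, a fit added after the data had been seen, 187 probe sets were higher and 99 lower in old stem cells, and all 104 of the first fit were among the 286. Leaving out 1 array of the blocked fit gave 148 to 270 calls for an old array, 66 and 72 for young 2 and 3, and 2776 for young 1, which leaves no age contrast inside the consecutive set. With young 2 and 3 averaged, 67 of the 286 passed. Within the consecutive arrays, 3 old against 1 young, limma called 229 higher and 52 lower, assuming that the lone young array varies like the old ones. Any peculiarity of that array counts as age there. Within the other arrays, 2 against 2, it called 595 higher and 160 lower, with the near-identical young 2 and 3 as the young side. The old minus young differences of the 2 sets of arrays over all tested probe sets correlated at r = 0.076, and 48.5% had the same direction. Other assignments of ages within the sets gave r from -0.31 to 0.31, so this does not decide whether the sets agree.

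The number of calls without the block depended on having both young 2 and young 3. Without young 3 no probe set passed in limma, and 1079 of 23725 tested had an unadjusted p under 0.05. That is no more than would be expected without differences. Without young 2 only 3 passed. With young 2 and 3 averaged to 1 replicate, 1 passed. The size of the named differences changed less than the number of calls. Without young 3 it was 5.01 for 1450653_AT, 5.00 for 1421065_AT and -4.62 for 1422247_A_AT, with adjusted p of 0.22, 0.20 and 0.14. Over 24 alternatives it ran from 3.66 to 5.59 for 1450653_AT, 3.66 to 5.50 for 1421065_AT and -5.05 to -3.23 for 1422247_A_AT. The smallest sizes came without old 1 and 2 for 1450653_AT and 1421065_AT, and without young 1 for 1422247_A_AT. Without young 1 there were 373 higher and 134 lower, without old 1 there were 81 and 43, and without old 2, 3, 4 or 5 there were 23 and 11, 18 and 9, 11 and 7, and 10 and 7.

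When the 8 arrays were divided into 5 and 3 in all 56 ways, the real ages gave the second highest count of calls.

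**Figure D3:**
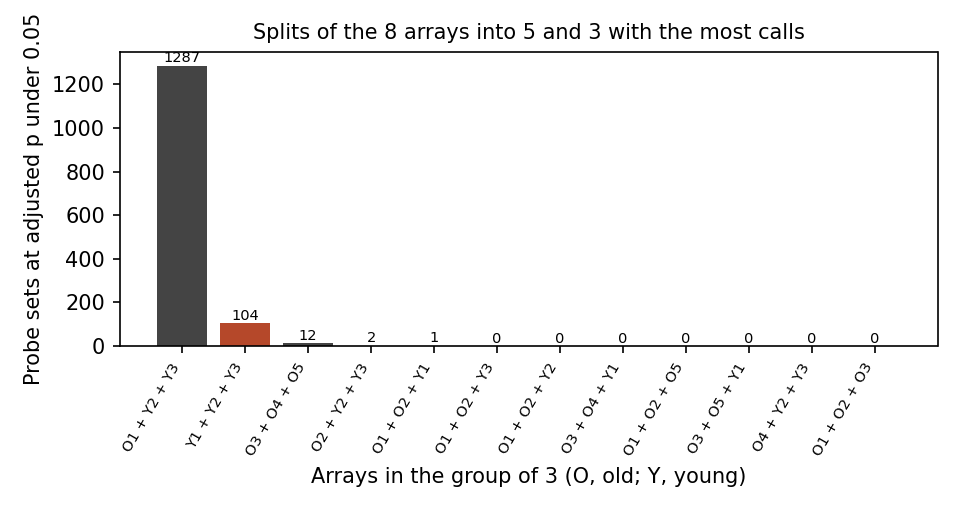
Probe sets at a limma adjusted p under 0.05 (vertical axis) for the 12 splits of the arrays into 5 and 3 with the most calls, by the arrays in the group of 3 (horizontal axis). Age (red) gave 104, the split of old 1 with young 2 and 3 gave 1287, and no other split gave more than 12.

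Glyceraldehyde-3-phosphate dehydrogenase (Gapdh), a glycolytic enzyme, beta-actin, a cytoskeletal protein, and the transferrin receptor, which takes up iron, are named on control probe sets of the array. Whether the identifiers match the values stays open, so the names are given only as listed. The Gapdh 3' control had a deposited intensity of 89.9 ± 115 (SD, n = 5) in old and 17.5 ± 15.1 (SD, n = 3) in young cells, a log2 difference of 1.80 (exact permutation p = 0.14, two-sided, adjusted 0.67 over 8 controls). Old 1 and 2 were at 80.2 and 291. Old 3 to 5 lay at 23.3 to 30.3, below young 1 (34.9) and above young 2 and 3 (9.2 and 8.4). The control for the middle of Gapdh had 47.9 ± 12.7 (SD, n = 5) and 35.6 ± 7.94 (SD, n = 3), with an exact permutation p of 0.20. The control for the B1 repeat, a short interspersed element, had 83.3 ± 70.7 (SD, n = 5) in old and 72.2 ± 22.7 (SD, n = 3) in young cells (exact permutation p = 0.82). Its old mean rests on old 1, at 207, and the log2 difference was -0.11, in the other direction. None of the 8 controls bright enough to test passed, and the lowest adjusted p was 0.67. The smallest possible permutation p was 0.0179, so 1 changed control alone could not have passed after adjustment over 8. The result is therefore no sign that the controls were unchanged.

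Several controls of named mouse transcripts were dim. The 3' beta-actin control lay between -3.6 and 9.7, at percentile 6.08 of all probe sets, and its 5' control between 13.9 and 26.2. All 3 transferrin receptor controls lay at percentile 3.67 of all probe sets or lower. Among the controls spiked into the sample, the pair for the 3' end of bioC, which are 2 probe sets for 1 bacterial transcript, had means of 576 and 18. No probe set outside the controls is given a gene name here.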

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

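The tests in this part were chosen after the results had been seen, except those on old array 1 alone and on the position of young array 1. Of 21 measures over the 5 old arrays, 2 had an array far from the others, and chance flags about 1 in 20. The Gapdh 3' control stood at 291 in old 2, against 80.2 in the next array. The B1 repeat control stood at 207 in old 1, against 61.6 in the next.

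A split of the arrays other than age gave more calls. Among the 56 splits into 5 and 3, age gave 70 higher and 34 lower probe sets. Counting the real one, 2 splits gave as many higher and 2 as many lower, a share under 0.05. That share takes all 8 arrays as separate and exchangeable, but young 2 and 3 were near-identical. Among the 6 splits with both in the group of 3, age ranked 2 by calls, so chance was not excluded. By an unadjusted p under 0.05 and by the share without overlap, 9 and 8 of the 55 other splits exceeded age. By those measures chance was not excluded either. With the near-identical young 2 and 3 averaged to 1 replicate, chance was not excluded. Of 21 splits, 2 gave as many calls as the 1 for age, and old 1 with old 2 gave 1405. Of the 8 arrays, the other split was old 1 with young 2 and 3, with 575 and 712, which points to a structure of the samples. Old 1 alone does not explain it. Without old 1, 1 of the other 34 splits again gave more calls than age, 1812 against 124, namely old 2 with young 2 and 3 against the consecutive title numbers. Among the 35 splits of all 8 arrays into 4 and 4, only 1, along the title numbers, gave as many as 1564 calls, and the highest other gave 0. Most of the 35 part young 2 from young 3 or divide old 3, 4 and 5, unlike this one. The grouping was also taken up after the data had been seen, so 1 of 35 does not exclude chance. This split test replaced a first test, which was undecided. The first asked whether the difference along the title numbers was alike in old and young arrays, needing a correlation above 0.3 and above 0.1 for each pair of single arrays, and it gave 0.23, with pairs from 0.015 to 0.33. A difference between the arrays with consecutive title numbers and the rest, of unknown origin, is a candidate explanation that these splits do not establish. It may be a sorting, amplification or hybridisation day, or a difference between groups of mice, which stays open. The title numbers alone do not fix this division, since that of young 2 stands close to the consecutive ones.

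Young 1 lay closer to old 3, 4 and 5 than to young 2 and 3. On the 507 probe sets called without it, its median position was 0.92 between young 2 and 3 (0) and old (1), as RNA of old cells would give by the bound of 0.75 set before, but young 2 and 3 are also outside its run of title numbers. With the run as a block, young 1 as labelled gave 286 calls and old 3, 4 or 5 in its place gave at most 0. A peculiarity of young 1 other than age could also give this, so it does not tell the age of its cells. This second test was added after the first had been seen, and its 4 assignments are too few for a share under 0.05. Old cells in young 1 and the run of title numbers therefore cannot be told apart. On the 124 probe sets called without old 1, old 1 lay at 0.88 between young (0) and old (1). Those were called with young 1 counted as young, so they cannot test an exchange of young 1 with old 1. The division that an exchange would give, old 1 with young 2 and 3, had 1287 calls against 104 for age. The run of title numbers, a wrong label of young 1 alone and its exchange with old 1 all stay open.

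Control probe sets sat at background, and copies of 1 control disagreed. The 21 pairs of probe sets for 1 end of 1 spiked transcript differed by 1.06 on the log2 scale on average, against 1.16 for shuffled pairs (permutation p = 0.22), but only 11 of the 45 spike probe sets lay above the pooled median, so most pairs could not show agreement. The 3' beta-actin control was above the 5' control in 0 of 8 arrays, but it sat at background, so this does not count against a loss of 5' ends in the amplification. The other transcripts with controls at both ends went both ways, with 3' above 5' in 8 of 8 arrays for 18S rRNA, 6 of 8 for Gapdh and 0 of 8 for pyruvate carboxylase and the transferrin receptor. Each compares 2 different probe sets. Probe set identifiers out of step with the values, a loss of 5' ends and spikes left out of the hybridisation all stay open, and these values decide none of them. Counts of called probe sets do not depend on the identifiers, apart from the 64 controls and the class endings.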

How the results depend on the processing

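The main counts were 70 higher and 34 lower. The values as deposited, arrays shifted to 1 median, a floor at the 40th percentile, no floor, no trend, a robust fit and the removal of _x_at and _s_at probe sets kept both within 1.5 times. The 1.5-fold minimum could not change either count, since the smallest called difference was 0.91 on the log2 scale. A floor at the 5th percentile gave 37 and 9, no filter 32 and 35, a filter at the 75th percentile 23 and 4, and an adjusted p under 0.01 gave 9 and 5. Array weights, from 0.16 for old 1 to 9.35 for young 2, gave 5248 and 5293. Such weights count closeness within a group as precision, and young 2 and 3 were near-identical. These counts are therefore no better estimate of the age difference. Leaving out 1 array in turn gave 0 to 373 higher and 0 to 134 lower. Among alternatives added after seeing the data, the run as a block gave 187 and 99 and old 1 and 2 left out gave 186 and 88. Young 2 and 3 averaged gave 1 and 0. There, 1054 of 23735 probe sets had an unadjusted p under 0.05, no more than expected without differences. Replicate numbers pair no samples, so no pairing was fitted. The cause of these changes was not tested, except that fewer probe sets or arrays entered some fits. The difference in 1426816_AT passed in all 20 alternatives that tested it, but the filter dropped it wherever a young array was left out or averaged, so its dependence on the young arrays was not tested. The other 3 named probe sets passed in 12 of 24 each, with adjusted p up to 0.23. None of the 4 reversed, which most alternatives could not have shown, since they were chosen for having no overlap. With independent noise, simulated 2-fold changes were recovered in 7.46% and 4-fold ones in 72.7%, so most 2-fold changes were out of reach in that setting. The planned tests of gene lists were not run, for lack of gene names.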

Other observations

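The test with young 2 and 3 averaged was chosen after its count for the real ages had been seen, and the block and its count of calls had been seen before its assignments were tested. Whether age acts alike in both sets of arrays was asked in 2 ways that share no array between the sets. Across all 24337 tested probe sets, the old minus young differences inside and outside the consecutive title numbers correlated at r = 0.076, with the same direction in 48.5%. The correlation ranked 6 of the 24 possible assignments of ages within the sets, where the highest other was 0.31 and the lowest -0.31. A broad age difference common to both sets was thus not seen. The bound set before, which counted all but the top 2 ranks against one, was too wide, since the real value lies within the spread of the other assignments, so the test decides nothing. A hypothesis was that a limited set of large age differences is shared. Of the 243 probe sets with the lowest p for age outside the consecutive numbers, 44.4% had the same direction inside, which ranked 18 of 24, with others from 18.5% to 81.5%. The hypothesis was not supported, and for the same reason not excluded.

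The blocked fit called 286 probe sets with the real ages, and only 1 of the 24 assignments gave as many, the real one, with 2 calls as the highest other. With young 2 and 3 as separate replicates, that is a share of 0.042, the smallest that 24 assignments allow. Most of the 24 assignments put the near-identical young 2 and 3 in different groups, unlike the real one. The share therefore does not exclude chance for that count. With young 2 and 3 averaged, the real ages gave 67 calls and the highest other gave 0, and the 12 assignments, of which only 1 gave as many, are too few for a share under 0.05. The young side of the consecutive set is 1 array.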
